A study of Mus musculus with 18 samples.

How the data were processed

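Gene expression was measured on 18 Agilent 4x44K mouse oligonucleotide arrays, each hybridised with 1 captured thyroid region in Cy5 and a common reference RNA in Cy3. Per the labels, the regions were cut by laser capture microdissection from frozen sections of thyroids of male C57BL/6 mice, RNA was extracted with Trizol, and antisense RNA was amplified with a RiboAmp kit and dye-labelled with an Arcturus kit. Per the labels, the reference was a commercial assorted RNA of Swiss Webster mice from embryo, brain, liver, kidney, lung, heart, thymus, spleen, ovary and testis. Thyroid is not among the tissues listed. No dyes were swapped, so a constant dye bias of a probe would drop out of differences between groups. One that varies between arrays would not. The Cy3 intensity of the brighter Calca probe was 18233 to 204897 on central and 259124 to 494049 on peripheral arrays. It thus followed the area compared, whereas the Cy3 intensity of the second Calca probe was 8088 to 29016 over all arrays.

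The deposited scanner files hold, per the file headers, spot intensity and local background intensity in both channels from Agilent Feature Extraction 9.5.1.1, while the submitters' processing notes name version 8.5.1.1. Per the file headers, the processed intensity in the same files was background-subtracted, spatially detrended and dye-normalized by linear and lowess steps within the array, and very low values were replaced by surrogates. The log10 ratio of processed Cy5 over processed Cy3 is, per the file headers, that program's own output, and the other deposited columns used are its flags for spots well above background, saturated spots, non-uniform spots and control spots. The authors also deposited a value table of linear ratios, for which no processing step is given in the sources used here. Its 40934 probes all matched the scanner files. Set against those files, each column of the table followed the Cy5 over Cy3 ratio after centring each probe, with correlations of 0.972 to 0.999, and the column medians ran from 0.871 on normal central 3 to 1.06 on dissected peripheral 4. Direction and linear scale were thus read from the values. What the authors did before the centring remained unknown, and the table was used only as an alternative.

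Each array held 45018 spots, of which 1639 were controls. The mean spot intensities were background-corrected with normexp at an offset of 50, fitted on all spots, and normalized within each array by loess of the log2 Cy5 over Cy3 ratio on the mean log2 intensity, with control spots at weight 0. Spots marked non-uniform were left out, at most 108 on any array, and saturated spots were kept. Spots of 1 probe were averaged. The 41174 gene probes were named by accession through a RefSeq gene table of the assembly GRCm38.p6 for 22951 probes, by a current symbol for 6659 and by an older symbol for 3109, and 8455 kept the name in the files. A probe was kept if its Cy5 signal was well above background on at least 3 arrays, which left 19082. The kept probe with the highest average intensity stood for its gene, giving 14664 genes. Probe positions are those of the scanner files, on the mouse build mm7 (NCBI35), and no genome of that build was used here, so the exon or untranslated region under a probe was not determined.

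The labels give 4 groups, namely normal central (n = 5), normal peripheral (n = 3), dissected central (n = 5) and dissected peripheral (n = 5). One linear model with the 4 group means was fitted to all arrays with limma 3.58.1 in R 4.3.3, files being read with the R package data.table (version 1.17.8). Tests were moderated with eBayes and adjusted by the Benjamini-Hochberg method over the 14664 genes, and a gene was called at an adjusted p under 0.05. The comparisons were dissected against normal in each area, central against peripheral in each state, the difference between the areas in the change after dissection, and an F test among the 4 groups. Gene lists were tested with camera at a preset correlation of 0.01 between genes and adjusted over the lists of a comparison, lists with under 4 measured genes being left out. Each list was tested again with the correlation estimated from the data. All p-values are two-sided unless stated otherwise. The labels do not tie regions to animals, so regions of different groups or of 1 group may come from the same mouse. The p-values measure the spread between captured regions and may be too small.

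Groups, comparisons, tests, the rule for named genes, the 22 gene lists and the alternatives were fixed before the data were examined. The lists held genes of thyroid hormone synthesis and thyrocyte identity, C cells and neuroendocrine cells, the cell cycle, the immediate early response, cAMP response, Wnt signalling, stem and progenitor cells, mesenchyme and extracellular matrix, epithelial junctions and keratins, growth factor signalling, endoplasmic reticulum chaperones and the unfolded protein response, hypoxia and glycolysis, oxidative phosphorylation, and, as markers of neighbouring tissue, macrophages, lymphocytes, parathyroid, skeletal muscle, adipocytes, endothelium, erythrocytes, airway epithelium and cartilage. Named genes were, per comparison, the 6 largest rises and 6 largest falls among called genes with a gene symbol and with no overlap between the arrays of both groups, or, where none passed, the 3 smallest p as values only. For each called list the 3 members with the smallest p were added. Tg, Slc5a5, Tshr, Pax8, Nkx2-1, Foxa2, Calca, Mki67 and Ccnd1 were added to each comparison of 2 groups whatever their p. Genes outside this rule were chosen after their values were seen. Slc5a5 had no probe past the filter, and 1 further gene that the rule names is not reported here.

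The model was tested on simulated log ratios for the 14664 genes with 200 of them changed 2-fold or 4-fold at once and noise independent between genes. The other measured cell cycle genes were raised as well, by less than 2-fold. The shares recovered are those of the 200, hold for about that number of changed genes and would be lower with few. Of the genes changed 2-fold, 75% were recovered in dissected against normal central, 62% in dissected against normal peripheral, 70% in central against peripheral of normal thyroid, 74% in that of dissected thyroid and 35% for the difference between areas. Of those changed 4-fold, 96%, 94%, 97%, 99% and 79% were recovered. False calls made up 6.42%, 8.62%, 3.95%, 4.32% and 6.56% of the calls in the same order, calls among the raised cell cycle genes counting in the total but not as false.

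The number of arrays limits the precision. The share of gene probes well above background in Cy5 ran from 24.7% on normal peripheral 1 to 44.0% on dissected peripheral 5. It was under 30% on 4 arrays, the others being dissected central 2 at 28.1%, dissected peripheral 1 at 28.7% and dissected central 1 at 29.5%. The lowest correlation between arrays was 0.964 for log2 Cy3 signal and 0.846 for log2 Cy5 signal. The median correlation of log ratios was 0.203 between arrays of 1 group and 0.0951 between arrays of different groups. The arrays lay on 5 slides scanned on 2 days, and every slide held at least 3 of the groups. Values are given with the slide as a block, and as differences within slides and within scan days.

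Alternatives were the Feature Extraction log ratio, median centring in place of loess, quantile scaling of average intensities (Aquantile), Cy5 alone with quantile normalization, no filter on dim probes, a filter on all 18 arrays, non-uniform spots kept, the mean over the probes of a gene, array weights, eBayes with trend and robust settings, a fit on the groups compared alone, the replicate number as a fixed block and as a random block within state, slide and scan day as blocks, the authors' value table, a fold of at least 2, the estimated correlation in camera, and each array left out in turn. After the data were examined, fits without the 4 weak arrays and on each scan day alone were added, as were effects averaged over areas or states and the parathyroid list without each array in turn.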

Results

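Expression was compared between the central and the peripheral area of the mouse thyroid lobe, in normal glands and in glands from which part had been removed by surgery (dissected, in the labels). The title of the series concerns thyroid cell proliferation following that operation, and its design text names a comparison among all 4 groups. Each of the 18 arrays carried RNA of 1 laser-captured area, with 5 arrays for normal central, 3 for normal peripheral, 5 for dissected central and 5 for dissected peripheral. The labels give neither the time after surgery nor the mouse each area came from, so areas may share animals and the p-values over captured areas may be too small. On the 18 arrays, 24.7% to 44.0% of gene probes were well above background in the tissue channel, Cy5. Values are log2 ratios of tissue over the common reference, and differences between groups are differences of these ratios. Across all genes the median difference lay between -0.02 and 0.01 in every comparison.

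The first question was how the central area of the normal lobe differs from its periphery. Genes of C cells, the calcitonin-secreting cells of the thyroid, were far higher in the central area. Calca, which encodes calcitonin, had a ratio of 3.22 ± 0.48 (SD, n = 5) in central and -0.62 ± 0.33 (SD, n = 3) in peripheral arrays, a 14.2-fold difference (log2 3.83, SE 0.71, limma adjusted p = 0.0367). The size of that difference depended on the reference channel, since with Cy5 alone it was 1.04 on the log2 scale and still called. The Cy3 intensity of this probe was 21951 to 52673 on central and 327125 to 494049 on peripheral arrays, although Cy3 held the same reference, and its Cy5 spot was saturated on normal central 3 and 4, so the fold is approximate. A second Calca probe, saturated on no array, with Cy5 intensities of 38955 to 110795 on central and 561 to 3939 on peripheral arrays, gave a log2 difference of 4.37. Chgb, a granin of secretory granules, rose 14.1-fold (log2 3.82, SE 0.53, adjusted p = 0.00827), from -2.71 ± 0.08 (SD, n = 3) to 1.11 ± 0.33 (SD, n = 5). The granin Scg3 rose 10.3-fold (log2 3.36, SE 0.50, adjusted p = 0.0151) and Pcsk2, a prohormone convertase, 8.43-fold (log2 3.08, SE 0.49, adjusted p = 0.0185). By the probe that stood for each gene, Cxcl13, a chemokine that attracts B cells, had the largest difference among the genes named, though a smaller one than the second Calca probe. Cxcl13 lay at 0.99 ± 0.49 (SD, n = 5) against -3.15 ± 0.26 (SD, n = 3), or 17.6-fold (log2 4.14, SE 0.49, adjusted p = 0.00186). Dner, a transmembrane protein with EGF repeats known from neurons, rose 9.98-fold (log2 3.32, SE 0.59, adjusted p = 0.0245), and by log2 2.68 on its second probe. Foxa2, a forkhead transcription factor of the endoderm, rose 8.28-fold (log2 3.05, SE 0.51, adjusted p = 0.0218). All 7 of these genes were higher in the central area on each of the 3 slides that held both areas. For genes picked by the rule of no overlap between arrays this follows by construction and tests no slide effect. On build mm7, the probes lie on chromosome 7 at 110549383 to 110549442 for Calca, chromosome 2 at 132535820 to 132535879 for Chgb, chromosome 9 at 75680654 to 75680713 for Scg3, chromosome 2 at 143554770 to 143554829 for Pcsk2, chromosome 5 at 95174192 to 95174251 for Cxcl13, chromosome 1 at 84583378 to 84583437 for Dner and chromosome 2 at 147783819 to 147783878 for Foxa2.

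As a group, 8 of the 18 measured C cell genes rose over all genes tested, and 15 rose adjusted over the list alone. The list median was 2.05 (camera adjusted p = 1.39e-26), and the call held with an estimated correlation between genes, at adjusted p = 0.0263. Further members that rose were Ddc, an amine-synthesising decarboxylase (log2 2.16, adjusted p = 0.0245), Snap25, a vesicle fusion protein (log2 2.09, adjusted p = 0.0245), and Gfra4, the persephin receptor (log2 2.01, adjusted p = 0.0403). Chga, another granin, differed by 2.90 with an adjusted p of 0.0595 and was not called. The mean of the list was 0.76 ± 0.31 (SD, n = 5) in normal central and -1.27 ± 0.34 (SD, n = 3) in normal peripheral arrays, and an exact permutation of the 8 arrays gave p = 0.0179, the smallest that 5 against 3 arrays can give. The difference of list means was 1.61 to 2.14 within slides, and 2.46 and 1.78 on scan days 1 and 2. With the slide as a block the list median was 1.96 (adjusted p = 1.70e-21).

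In all, 41 of 14664 genes differed between the normal areas at an adjusted p under 0.05, and all 41 were higher in the central area. Arrays of the 2 areas did not overlap for 712 genes, 4.86% of those tested, where chance gives 3.57%. The half-width of the 95% interval of a typical gene was 0.47 on the log2 scale. A fit with slide as a block called 18 genes, 17 of them higher in the central area, and 15 of the 18 were among the 41. Under the block Calca had an adjusted p of 0.120 (log2 3.53) and Foxa2 one of 0.0534 (log2 2.87), so both calls were lost, while Cxcl13 stayed called at 0.0179, as did Chgb and Scg3 at 0.0409 and Dner and Pcsk2 at 0.0478. The count depended on single arrays. It was 2 without normal central 1, 13 without normal central 2, 2 without normal central 3, 9 without normal central 4, 27 without normal central 5, 1 without normal peripheral 2 and 6 without normal peripheral 3. Through the shared spread it was also 24 without dissected central 1, 76 without dissected central 2, 25 without dissected peripheral 1, 22 without dissected peripheral 2, 25 without dissected peripheral 4 and 27 without dissected peripheral 5. Cxcl13 stayed called whichever array was left out, Calca lost its call without any 1 of the 8 arrays compared (adjusted p = 0.0581 to 0.154), and Chgb lost it without normal peripheral 2 (adjusted p = 0.0723). Scg3 lost its call without normal central 1 or 3 or normal peripheral 2 (adjusted p = 0.0518 to 0.0773), and Pcsk2 without these or normal peripheral 3 (adjusted p = 0.0518 to 0.144). Foxa2 lost its call without normal central 1, 3 or 4 or normal peripheral 2 or 3 (adjusted p = 0.0518 to 0.154), and Dner without these or normal central 2 (adjusted p = 0.0501 to 0.154). Calca was also lost without dissected peripheral 1, 2 or 4 (adjusted p = 0.0510 to 0.0553). With no filter on dim probes Calca (adjusted p = 0.107), Dner (0.0779) and Foxa2 (0.0687) were not called. Without the 4 weak arrays 95 genes were called, 39 of them among the 41, whereas scan day 1 alone gave 1 and scan day 2 alone 0.

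The same comparison in dissected thyroid gave the same direction for these genes. Calca differed 22.6-fold (log2 4.50, SE 0.66, limma adjusted p = 0.00308), with 2.54 ± 2.11 (SD, n = 4) in central and -1.95 ± 0.50 (SD, n = 5) in peripheral arrays, its spot on dissected central 1 having been left out as non-uniform. Cxcl13 differed 22.4-fold (log2 4.48, SE 0.42, adjusted p = 6.89e-05), at 0.02 ± 1.20 against -4.47 ± 0.40 (SD, n = 5 each). Scg3 rose 14.2-fold (log2 3.83, SE 0.43, adjusted p = 0.00035), Dner 11.2-fold (log2 3.49, SE 0.51, adjusted p = 0.00259, second probe 2.84) and Pcsk2 10.5-fold (log2 3.40, SE 0.42, adjusted p = 0.00083). Chgb rose by 3.81 on the log2 scale (SE 0.46, adjusted p = 0.000585). Chga rose 11.3-fold (SE of the log2 difference 0.53, adjusted p = 0.00332), with its probe on chromosome 12 at 100060167 to 100060226. Foxa2 rose 8.84-fold (log2 3.14, SE 0.44, adjusted p = 0.00243). With Cy5 alone the log2 difference of Calca was 1.24, again called, and without dissected central 2 it was 5.53. The Cy3 intensity of its probe was 18233 to 204897 on central and 259124 to 415403 on peripheral arrays, and the second Calca probe, with a Cy3 intensity of 8088 to 29016, gave 4.22. Each of the 8 genes was higher in the central area on all slides compared, 4 for Calca and 5 for the others. For genes picked by the rule of no overlap this again follows by construction. Each of the 8 stayed called with the slide as a block, Calca with the largest of these adjusted p at 0.0148. On the arrays of dissected thyroid alone the calls of Calca (adjusted p = 0.0671) and Dner (adjusted p = 0.0548) were lost, as was that of Chga on scan day 1 (adjusted p = 0.201) and all of them on scan day 2.

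**Figure D1:**
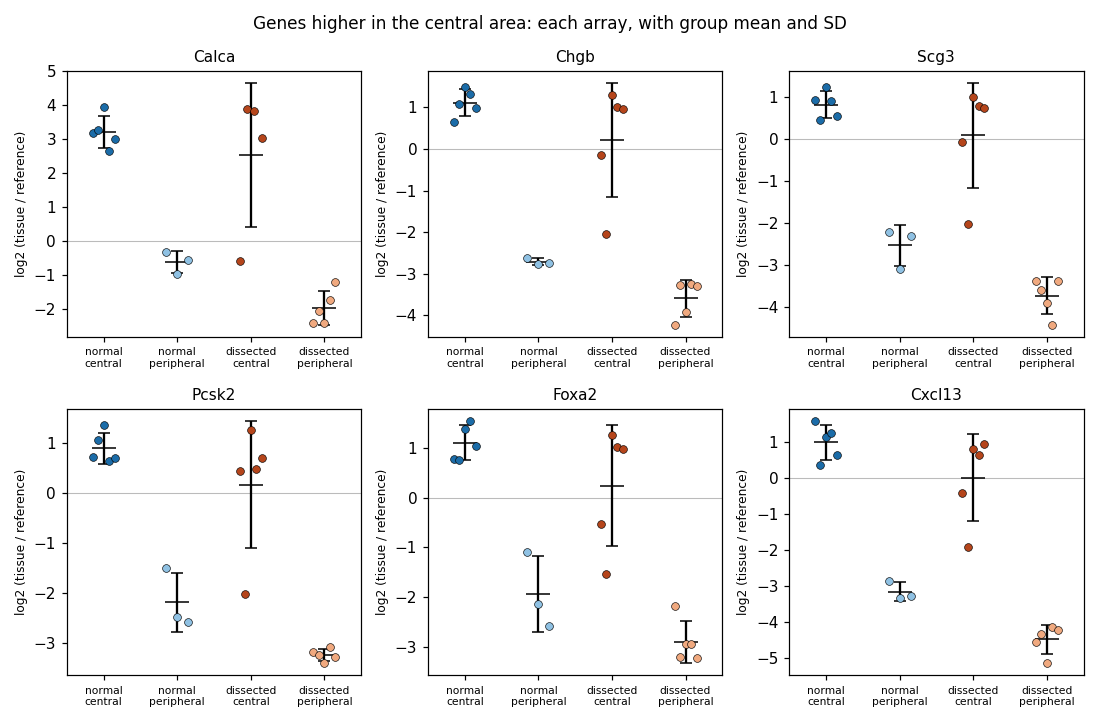
Log2 ratios of tissue over reference of Calca, Chgb, Scg3, Pcsk2, Foxa2 and Cxcl13 on every array in the 4 groups, with points for arrays and the mean ± SD of each group. Cxcl13 lay at 0.99 and 0.02 on average in the normal and dissected central groups and at -3.15 and -4.47 in the peripheral ones.

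Of the 18 measured C cell genes, 10 rose in the central area of dissected thyroid, and 15 rose adjusted over the list alone. The list median was 1.79 (camera adjusted p = 1.04e-36), and adjusted p = 0.0066 with an estimated correlation. List means were 0.20 ± 0.82 (SD, n = 5) in central and -1.87 ± 0.18 (SD, n = 5) in peripheral arrays, with p = 0.00794 by exact permutation, the smallest that 5 against 5 arrays can give. The central mean was higher on 5 of 5 slides, by 0.75 to 2.91, and by 2.64 and 1.68 on scan days 1 and 2. With the slide as a block the adjusted p was 2.6e-32. The median of 1.79 stayed the same by construction, as both dissected groups had an array on each slide. The immediate early list, genes induced within minutes of stimulation, was lower in the central area, with a median of -0.26 (camera adjusted p = 0.0105) and 2 of 19 members above 0. That call was lost at adjusted p = 0.356 with an estimated correlation, and no member fell over all genes or adjusted over the list alone. With the slide as a block the adjusted p was 0.00468, the median of -0.26 again staying the same by construction. The mean of that list was lower on 5 of 5 slides, and by -0.13 and -0.32 on the scan days. Its members with the smallest p were Zfp36, an mRNA decay factor (-0.40, SE 0.17), and the transcription factors Klf6 (-0.66, SE 0.35, but -0.13 by its second probe) and Myc (-0.31, SE 0.20, but -0.05 and 0.22 by its other probes). Over the other settings Zfp36 ran from -0.60 to -0.20, Klf6 from -0.97 to -0.39 and Myc from -0.66 to 0.38. The call was lost without dissected central 5 (median -0.17, adjusted p = 0.104), without dissected peripheral 1 (median -0.20, adjusted p = 0.0707) and without dissected peripheral 2 (median -0.17, adjusted p = 0.0718).

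Between the areas of dissected thyroid 86 genes differed, all 86 higher in the central area. Arrays of the areas did not overlap for 245 genes, 1.67% against 0.794% by chance, and the typical half-width of the 95% interval was 0.41. Blocking on slide gave 89 genes, 85 of them higher and 71 shared with the 86. The count was 173 without dissected central 2, on which C cell genes were low, and 47, 52 and 53 without dissected central 3, 4 and 5. It was 56 without dissected peripheral 2 and 52 without dissected peripheral 3. Without the 4 weak arrays it was 193, of which 84 were among the 86, and it was 26 on scan day 1 alone and 0 on scan day 2 alone.

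The calls of both states overlapped. Of the 41 genes called in normal and the 86 called in dissected thyroid, 33 were called in both, where 0.240 would be shared by independent lists (one-sided Fisher's exact p = 1.78e-69). These comparisons share no arrays, but both used the spread of each gene estimated over all arrays. Genes with a small spread were thus favoured in both, and the lists are not fully independent. Fisher's exact test also treats genes as independent, so its p may be too small. All 53 genes called in dissected thyroid alone had the same sign in normal thyroid. Across genes, which are not independent replicates, the central minus peripheral differences of normal and dissected thyroid correlated at 0.348. Of the 94 genes called in either state, 10 belonged to the C cell list.

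**Figure D2:**
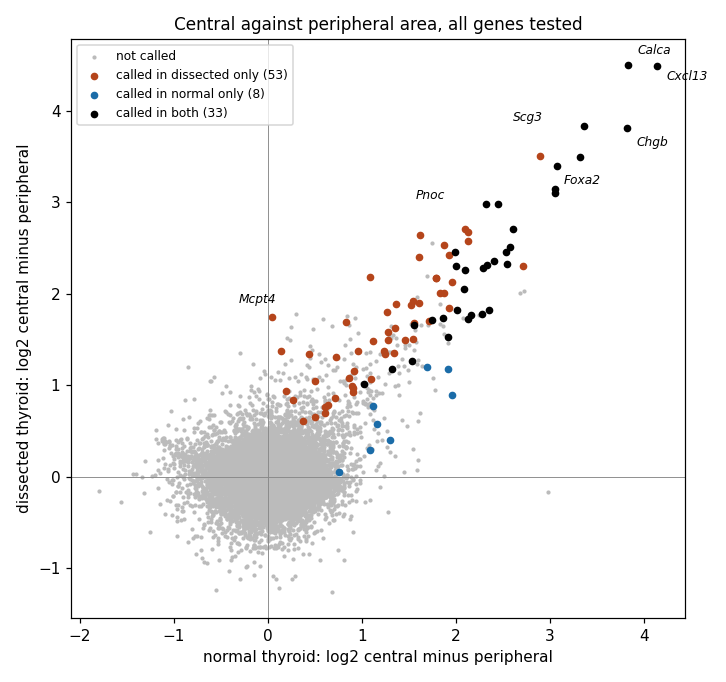
Central minus peripheral log2 difference of each gene in normal thyroid (x axis) against that in dissected thyroid (y axis), with genes called in both states, in dissected alone and in normal alone marked. The 33 genes called in both states lay above 0 on both axes, as did the 53 called in dissected thyroid alone.

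No thyrocyte gene named here was called between areas. Tg, the thyroglobulin from which thyroid hormone is made, differed by -0.17 (SE 0.36, limma adjusted p = 0.938) in normal and -0.67 (SE 0.31, adjusted p = 0.667) in dissected thyroid. Differences of Tshr, the thyrotropin receptor, which was not well above background on any normal peripheral array, were 0.17 and -0.05, those of the transcription factor Pax8 were 0.20 and -0.04, and those of Nkx2-1, another thyroid transcription factor, 0.12 and -0.18. For Mki67, a marker of cycling cells, the differences were -0.01 (SE 0.50) and 0.49 (SE 0.43), and for Ccnd1, cyclin D1, 0.09 (SE 0.18) and 0.00 (SE 0.15). With each array left out Tg ran from -0.50 to 0.19 in normal and -0.83 to -0.34 in dissected thyroid, Nkx2-1 from -0.19 to 0.35 and -0.29 to -0.11, and Mki67 from -0.33 to 0.28 and 0.31 to 0.72. Over all other settings Tshr ran from -0.07 to 1.06 in normal and -0.20 to 0.07 in dissected thyroid. Pax8 ran from 0.04 to 0.74 and -0.15 to 0.16, and Ccnd1 from 0.02 to 0.41 and -0.15 to 0.13. The thyrocyte list, with 19 of 23 genes measured, had medians of -0.09 (adjusted p = 0.617) and -0.20 (adjusted p = 0.0943) and was not called by camera. The mean of that list was nevertheless lower in the central area of dissected thyroid, at -0.02 ± 0.09 against 0.13 ± 0.09 (SD, n = 5 each), on 5 of 5 slides and with no overlap between arrays (exact permutation p = 0.00794, the smallest 5 against 5 can give, and 0.0582 adjusted over 22 lists). In normal thyroid the difference of means was -0.04 (exact permutation p = 0.732). The cell cycle list, with 26 of 33 genes measured, had medians of 0.15 (adjusted p = 0.176) and 0.01 (adjusted p = 0.97).

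**Figure D3:**
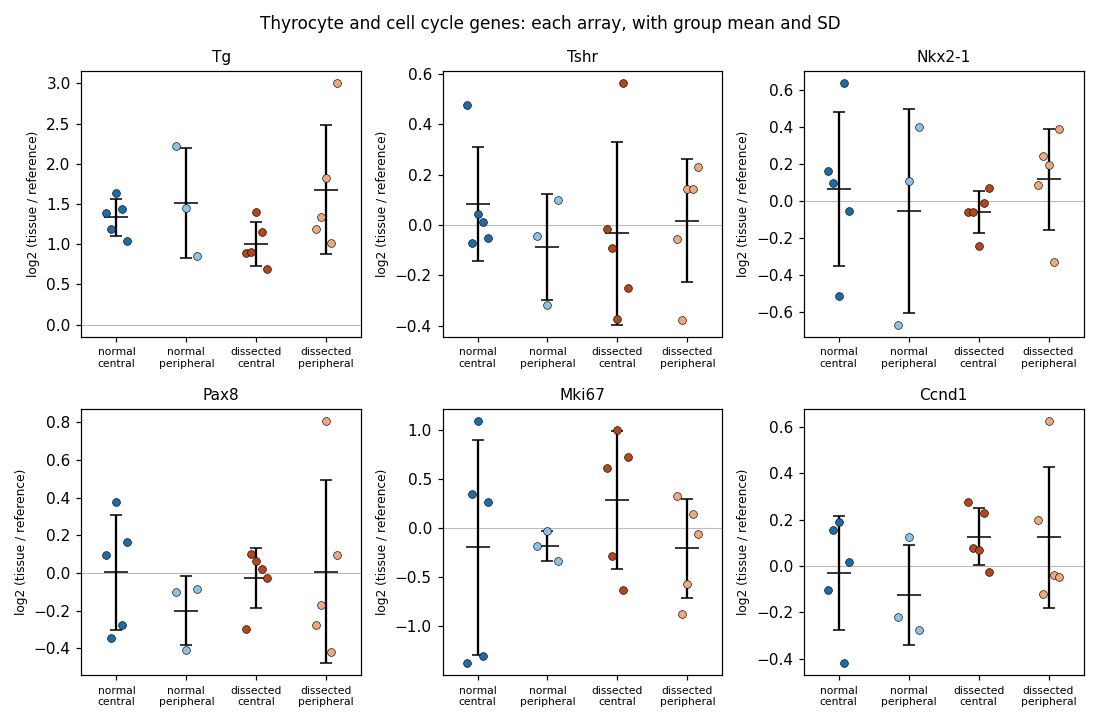
Log2 ratios of tissue over reference of Tg, Tshr, Nkx2-1, Pax8, Mki67 and Ccnd1 on every array in the 4 groups, with points for arrays and the mean ± SD of each group. None of the 6 genes was called between any pair of groups compared, and Mki67 varied most within normal central arrays, with an SD of 1.09, while Tshr was not well above background on normal peripheral arrays.

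After partial thyroidectomy no single gene of the central area passed the threshold. The genes with the smallest p were Jdp2, a repressor of AP-1 transcription (0.80, SE 0.13, limma adjusted p = 0.114), Nupr1l, a relative of the stress gene Nupr1 (-1.07, SE 0.18, adjusted p = 0.114), and Mfsd2a, a lysophospholipid transporter (1.96, SE 0.36, adjusted p = 0.171). Jdp2 lay at 0.19 ± 0.11 in dissected and -0.60 ± 0.15 in normal central arrays (SD, n = 5 each), with a higher dissected value on 5 of 5 slides and differences of 0.87 and 0.75 on the scan days. Nupr1l lay at -0.56 ± 0.44 against 0.51 ± 0.18 and Mfsd2a at 0.36 ± 0.21 against -1.60 ± 0.56 (SD, n = 5 each), lower and higher on 5 of 5 slides, respectively. Without dissected central 3, Nupr1l was called (log2 -1.20, adjusted p = 0.0376). Their probes lie on mm7 chromosome 12 at 83641187 to 83641246, chromosome 5 at 129148974 to 129149033 and chromosome 4 at 122391585 to 122391644. Tg differed by -0.33 (SE 0.31), Nkx2-1 by -0.13 (SE 0.21), Foxa2 by -0.86 (SE 0.44), Calca by -0.67 (SE 0.66), Mki67 by 0.48 (SE 0.43) and Ccnd1 by 0.16 (SE 0.15), with adjusted p of 0.959 for Foxa2 and 0.998 for the rest. Differences were -0.12 for Tshr and -0.03 for Pax8. Single arrays moved several of these values. Without dissected central 2 Calca was 0.37, its sign turned, and Foxa2 -0.42, whereas the second Calca probe gave -1.01 on all arrays. Without normal central 1 Mki67 was 0.19 and Tshr -0.02, without normal central 3 Mki67 was 0.80 and Pax8 0.06, and without normal central 4 Nkx2-1 was 0.02 and Ccnd1 0.06.

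In that comparison limma called 0 of 14664 genes, and 766 genes, 5.22%, had an unadjusted p under 0.05. Arrays did not overlap for 147 genes, 1.00% against 0.794% by chance. Blocking on slide also gave 0, with 962 genes at an unadjusted p under 0.05. Without dissected central 2 or without dissected central 3 the count was 1, and with array weights it was 2. Simulated data of this size had 200 genes and the cell cycle list changed at once, with noise independent between genes. There, 75% of the 2-fold changes among the 200 were recovered. With fewer genes changed the adjustment is stricter, so that share does not hold for a comparison with few changes.

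At the level of gene lists, 4 shifted in the central area after dissection. The C cell list was lower, with a median of -0.64 (camera adjusted p = 0.000204, but adjusted p = 0.882 with an estimated correlation) and 2 of 18 members above 0. Ddc differed by -0.88, Snap25 by -0.74 and Sst, the somatostatin gene, by -1.32, none of them called. Across the settings these ran from -1.17 to -0.45, from -1.18 to -0.29 and from -2.51 to -0.81, in the same order. The endoplasmic reticulum chaperone and unfolded protein response list was higher, with a median of 0.14 (adjusted p = 0.0153) and 16 of 20 members above 0, among them Herpud1 (0.85), Creld2 (0.42) and Hyou1 (0.42), which act in protein folding and degradation there. That call was lost at adjusted p = 0.923 with an estimated correlation. The macrophage list had a median of 0.14 (adjusted p = 0.0129, but adjusted p = 0.882 with an estimated correlation) and 13 of 17 members above 0. Its members with the smallest p were Adgre1, the F4/80 antigen (0.91), Tyrobp, a signalling adaptor (0.44), and Lgals3, galectin-3 (0.59). The skeletal muscle list had a median of 0.36 (adjusted p = 0.00283, but adjusted p = 0.882 with an estimated correlation) and 11 of 12 members above 0, with Myh4, a fast myosin (2.16, SE 1.09), Ttn, titin (0.48), and Acta1, skeletal actin (0.24). All 4 calls were thus lost with an estimated correlation. No member of any of the 4 lists rose or fell, over all genes or adjusted over the list alone.

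The 4 medians were unaltered when the slide was a block. This follows by construction, as both central groups had an array on each slide, and tests no slide effect. The adjusted p under the block were 0.000281, 0.0207, 0.0129 and 0.0061 in the same order. Within slides, the dissected minus normal difference of the C cell list mean was above 0 on 2 of 5, from -1.91 to 0.25, and it was -0.21 and -0.80 on the scan days. The chaperone list mean was higher on 4 of 5 slides, by 0.37 on scan day 1 and 0.03 on day 2. That of the macrophage list was higher on 4 of 5 slides, by 0.07 and 0.29 on the days, and that of the muscle list on 3 of 5, by -0.09 and 1.07. The C cell call rested on dissected central 2, where the list mean was -1.15 against -0.02 to 0.85 on the other 4 dissected central arrays. Without it the median was -0.19 (adjusted p = 0.495), and without the 4 weak arrays -0.05 (adjusted p = 0.832). The muscle call was lost without the same array (median 0.27, adjusted p = 0.326), and its median was 0.56 without dissected central 4 and 0.57 without normal central 4. The chaperone call was lost without dissected central 2, 3 or 4 (adjusted p = 0.0957, 0.265 and 0.112) and without normal central 2, 4 or 5 (adjusted p = 0.134, 0.0599 and 0.406), while its median was 0.22 without dissected central 1 and 0.27 without normal central 1. The macrophage call was lost without dissected central 1, 2 or 3 (adjusted p = 0.0536, 0.0957 and 0.149) and without normal central 4 or 5 (adjusted p = 0.0599 and 0.118). Its median was 0.25 without dissected central 4, 0.23 without dissected central 5 and 0.29 without normal central 3.

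**Figure D4:**
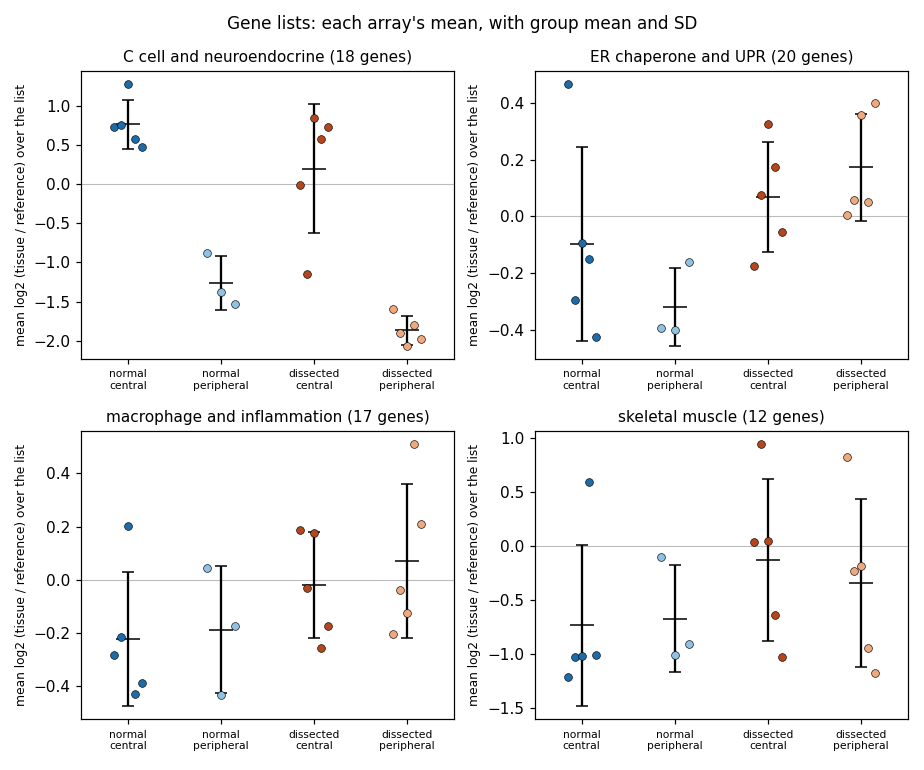
Mean log2 ratio of the C cell, endoplasmic reticulum (ER) chaperone and unfolded protein response (UPR), macrophage and skeletal muscle lists on every array in the 4 groups, with points for arrays and the mean ± SD of each group. The C cell mean was -1.15 on 1 dissected central array, and the chaperone mean ran from -0.32 on average in normal peripheral to 0.17 in dissected peripheral arrays.

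In the peripheral area, too, single genes did not pass. The smallest p belonged to Sqstm1, the autophagy receptor p62, at 0.62 ± 0.09 (SD, n = 5) in dissected and -0.32 ± 0.54 (SD, n = 3) in normal arrays (0.94, SE 0.18, limma adjusted p = 0.304). It was followed by Zfp580, a zinc finger protein (-0.95, SE 0.18), and Pcbd1, an enzyme of tetrahydrobiopterin recycling (-0.98, SE 0.20), with the same adjusted p. Sqstm1 was higher and both others lower on 3 of 3 slides. Their probes lie on mm7 chromosome 11 at 50156925 to 50156984, chromosome 7 at 4630560 to 4630619 and chromosome 10 at 60611741 to 60611800. Differences were 0.17 (SE 0.36) for Tg, 0.10 for Tshr, 0.21 for Pax8, 0.17 for Nkx2-1, -0.96 (SE 0.51) for Foxa2, -1.33 (SE 0.71) for Calca, -0.02 (SE 0.50) for Mki67 and 0.25 (SE 0.18) for Ccnd1, with adjusted p from 0.629 to 0.997. The second Calca probe gave -0.86. Without normal peripheral 1 Sqstm1 was 0.63, Tg 0.53, Foxa2 -0.54 and Nkx2-1 -0.14, and without dissected peripheral 5 Tg was -0.16. With each array left out Mki67 ran from -0.15 to 0.15, Pax8 from 0.01 to 0.31, Tshr from -0.01 to 0.20 and Ccnd1 from 0.12 to 0.37.

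Here limma called 0 genes, with 1225 (8.35%) at an unadjusted p under 0.05. Arrays did not overlap for 618 genes, 4.21% against 3.57% by chance. With the slide as a block 0 were called, with 1495 at an unadjusted p under 0.05, and without normal peripheral 3 the count was 1. The typical half-width of the 95% interval was 0.47 here and 0.41 in the central area.

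In the peripheral area the chaperone list had the smallest camera p. Its median was 0.43 (camera adjusted p = 7.28e-07), with 18 of 20 members above 0, and while 0 members rose over all genes, 5 rose adjusted over the list alone. The call was lost at adjusted p = 0.741 with an estimated correlation. Its members with the smallest p were Edem1, which sends misfolded glycoproteins to degradation (0.72, SE 0.19, adjusted p = 0.386), Hspa5, the chaperone BiP (1.39, SE 0.37, adjusted p = 0.386), and Dnajb9, a BiP cochaperone (0.92, SE 0.27, adjusted p = 0.454). Other probes gave 0.25 and 0.33 for Edem1 and 0.44 and 0.58 for Dnajb9, and without normal peripheral 1 Hspa5 was 0.87 and Dnajb9 0.62. List means were 0.17 ± 0.19 (SD, n = 5) in dissected and -0.32 ± 0.14 (SD, n = 3) in normal peripheral arrays. The C cell list was lower, with a median of -0.59 (adjusted p = 0.00082, but adjusted p = 0.741 with an estimated correlation). Scg3 differed by -1.20, Chga by -1.39 and Pcsk1, a prohormone convertase, by -1.09 (-0.60 by its second probe), none of them called, and no member fell adjusted over the list alone. With the slide as a block the medians were 0.35 (adjusted p = 2.36e-05) and -0.66 (adjusted p = 0.000163). The chaperone mean was higher on 3 of 3 slides, by 0.36 and 0.55 on the scan days, and the C cell mean higher on 0 of 3, differing by -0.39 and -0.70. Without normal peripheral 1, the array with the fewest probes above background, the C cell median was -0.23 (adjusted p = 0.0967). Without normal peripheral 2 the chaperone median was 0.28 (adjusted p = 0.00183).

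Whether the areas changed differently after dissection was tested directly. The interaction gave 0 genes by limma, with 852 at an unadjusted p under 0.05, a smallest adjusted p of 0.790 and a typical half-width of 0.63. It also gave 0 with the slide as a block, with 1213 at an unadjusted p under 0.05. The smallest p belonged to Ly6g6e, a member of the Ly6 family, which differed by -0.66 in the central and 0.66 in the peripheral area (difference -1.32, SE 0.29). Next came Medag (1.17, SE 0.26), whose second probe gave 0.18, and Dusp22, a dual-specificity phosphatase (-0.93, SE 0.21). Across genes, the changes of the 2 areas correlated at 0.0679. No list differed, the smallest adjusted p being 0.0995 for the chaperone list at a median of -0.21.

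Among the 4 groups together, 155 genes differed by limma's F test, and 130 with the slide as a block, of which 113 were shared. Of the 155, 91 were also called between areas, and 47 had an unadjusted p under 0.05 for dissection in an area. Over all 14664 genes, 766 in the central and 1225 in the peripheral area had such a p. The F test picked the 155 on the same group means, so the 47 are no separate evidence of a change after dissection. On scan day 1 alone 16 genes were called and on scan day 2 alone 0.

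Lists tied to growth were not called after dissection, with values given for the central and then the peripheral area. Medians were -0.06 (adjusted p = 0.460) and 0.14 (adjusted p = 0.476) for the cell cycle, of which 1 gene rose adjusted over the list alone in the peripheral area, and -0.02 (adjusted p = 0.978) and 0.17 (adjusted p = 0.624) for thyrocyte genes. They were -0.02 (0.916) and 0.07 (0.395) for immediate early genes, 0.06 (0.916) and 0.09 (0.903) for cAMP response, and -0.07 (0.726) and 0.03 (0.624) for Wnt signalling, adjusted p standing in parentheses. Growth factor genes gave -0.07 (0.583) and -0.22 (0.417), stem and progenitor genes -0.06 (0.916) and 0.07 (0.979), mesenchymal genes 0.02 (0.541) and 0.01 (0.641), and epithelial genes 0.01 (0.702) and 0.20 (0.101). Hypoxia genes gave 0.04 (0.460) and 0.15 (0.241) and oxidative phosphorylation genes 0.06 (0.446) and 0.13 (0.693). With the slide as a block the immediate early list was called in the peripheral area, at a median of 0.17 (adjusted p = 0.0445).

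The same lists between areas, in normal and then in dissected thyroid, were not called either, apart from the immediate early genes of dissected thyroid. Medians were -0.10 (0.921) and -0.16 (0.934) for cAMP response, 0.03 (0.921) and -0.09 (0.375) for Wnt signalling, and 0.14 (0.293) and 0.14 (0.169) for stem and progenitor genes, of which Foxa2 rose in both states. They were 0.05 (0.804) and 0.04 (0.436) for mesenchymal genes, 0.00 (0.945) and -0.17 (0.0943) for epithelial genes and -0.08 (0.735) and -0.06 (0.950) for growth factor genes. Chaperone genes gave 0.15 (0.176) and -0.11 (0.375), hypoxia genes -0.18 (0.617) and -0.14 (0.0943), oxidative phosphorylation genes 0.08 (0.921) and 0.04 (0.908), and immediate early genes of normal thyroid -0.02 (0.529).

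Markers of neighbouring tissues were measured in the same way. After dissection, medians in the central and peripheral area were -0.17 (0.221) and -0.23 (0.624) for lymphocytes, 0.18 (0.446) and -0.18 (0.565) for adipocytes, 0.01 (0.404) and -0.03 (0.641) for endothelium, and -0.00 (0.884) and -0.19 (0.689) for erythrocytes. They were -0.13 (0.573) and 0.69 (0.641) for airway epithelium and 0.02 (0.916) and 0.02 (0.979) for cartilage, and in the peripheral area 0.18 (0.101) for macrophages and 0.19 (0.624) for muscle. Between areas, in normal and dissected thyroid, they were 0.13 (0.945) and -0.08 (0.759) for lymphocytes, -0.35 (0.209) and 0.05 (0.950) for adipocytes, 0.01 (0.735) and 0.14 (0.354) for endothelium, and -0.15 (0.694) and 0.10 (0.950) for erythrocytes. Airway genes gave 1.02 (0.299) and 0.04 (0.908), cartilage genes -0.36 (0.617) and -0.28 (0.442), macrophage genes -0.05 (0.617) and -0.00 (0.436), and muscle genes -0.04 (0.660) and 0.16 (0.436). The parathyroid list had 2 of 5 genes measured and was not tested, with medians of -0.79 and -0.47 after dissection and 0.62 and 0.30 between areas. Without normal central 3, an omission chosen after the values were seen, the -0.79 in the central area became 0.07 and the 0.62 between normal areas became -0.24, so both signs rested on that array. Without normal peripheral 1 the -0.47 became -0.11.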

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

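The tests of the reference channel reported here were chosen only after its values were seen.

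Thyroid and parathyroid genes were bright in the Cy3 channel, which held the common reference and was not otherwise analysed. Of 12 such markers, 7 were well above background in Cy3 on all 18 arrays, with median Cy3 intensities that included 152051 for Calca, 79154 for Tg, 19419 for Cdh16, 5917 for Dio1, 2193 for Pth and 235 for Iyd. For the parathyroid hormone gene Pth, signal of the tissue dye read in the reference channel is argued against, since this gene was well above background in Cy3 but not in Cy5 on 12 arrays. A reference that may have been richer in thyroid than its label says stays open. Against 14 of 64 markers of other tissues above background on all arrays, two-sided Fisher's exact p was 0.0155, but 0.382 without the 4 markers whose brightness prompted the test. The 3 of the 8 left that were above background on all arrays, Cdh16, Dio1 and Iyd, are also expressed in kidney or liver. The label lists both, but only 2 of 11 liver markers and 3 of 8 kidney markers, Cdh16 among these, were so. Median Cy3 intensities were 120 for Alb and 101 for Umod, against 1625 for Apoc1 and 1042 for Napsa. The test counted presence and not brightness, and the thyroid markers Foxe1 and Duox2 were dim in Cy5 too, at medians of 111 and 115. It could thus miss thyroid RNA in the reference, and no biological explanation was tested.

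Of 144 groups of 4 or more arrays tested for 1 array standing apart, 12 had one, where chance gives about 7.2, and these fell on 8 arrays. On normal central 3, Chga was 2.60 against 0.22 on the nearest other array and Sqstm1 0.31 against 0.13. That array also had a Cy5 intensity of 58320 for Pth, against 82.0 to 169 on the others. On normal central 4, the skeletal muscle list had a mean of 0.60 against -1.01 and its member Myh4 0.70 against -2.97. Tshr was 0.48 on normal central 1, against 0.04. On dissected central 2, Pcsk2 was -2.02 against 0.43 and Pcsk1 -1.63 against 0.46. Edem1 was -0.48 on dissected central 1, against -0.11. Sst was 2.38 on dissected central 5, against -0.84, and -1.42 on dissected peripheral 1, against -2.28. On dissected peripheral 1 Foxa2 was -2.18, against -2.94. Ly6g6e was 0.57 on dissected peripheral 3, against 0.12.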

How the results depend on the processing

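Of the tests below, those without the 4 weak arrays and on each scan day alone were chosen only after the results were seen. Aquantile leaves log ratios as they are by construction and tests nothing.

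Genes called in dissected against normal central thyroid numbered 2 with array weights and 0 to 1 with each array left out, and in the peripheral area 1 with the Feature Extraction ratio, 5 with median centring, 1 in the authors' value table and 0 to 1 with each array left out. Between the normal areas the count of 41 became 78 with the Feature Extraction ratio (36 shared), 153 with median centring (41 shared), 8 with no filter, 18 with slide as a block, 85 in the value table, 95 without the 4 weak arrays, 1 on scan day 1, 0 on scan day 2, and 1 to 76 with each array left out. Between the dissected areas the count of 86 became 47 with median centring, 45 with Cy5 alone, 35 with the filter on all 18 arrays, 55 with array weights, 21 on the arrays compared alone, 193 without the weak arrays, 26 and 0 on the scan days, and 47 to 173 with each array left out. The interaction gave 4 genes with median centring and 0 in every other setting, each array left out included. The 4-group count of 155 became 57 with the filter on all arrays, 16 and 0 on the scan days, and 107 to 185 with each array left out. The fits with fewer arrays or genes change the error by construction, and the other causes were not tested.

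Lists called in dissected against normal central thyroid (4) became 1 with no filter, without the weak arrays and on scan day 1, 0 with an estimated correlation, and 0 to 5 with each array left out. In the peripheral area (2) they became 4 with median centring and without the weak arrays, 7 with array weights, 0 with an estimated correlation and 2 to 4 with each array left out. Between the normal areas (1) they became 3 with median centring and with no filter, 2 with the filter on all arrays and on the arrays compared alone, 5 with array weights, 4 without the weak arrays and on scan day 2, and 1 to 4 with each array left out. Between the dissected areas (2) they became 1 in the value table and with an estimated correlation, and 1 to 6 with each array left out. For the interaction (0) they became 2 with median centring and without the weak arrays, 1 with no filter and on either scan day, 3 with array weights, and 0 to 5 with each array left out. The C cell list by area was called in all 38 settings, with medians of 1.67 to 2.97 in normal and 1.38 to 2.81 in dissected thyroid.

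Without loess, median centring moved the median difference of all genes to -0.15 and 0.23 after dissection in the central and peripheral area, 0.28 and -0.12 between the areas of normal and dissected thyroid, and -0.40 for the interaction, and its counts are to be read against these shifts. In the value table these medians were 0.11 in the peripheral area after dissection, 0.13 between normal areas and -0.15 for the interaction, and the Feature Extraction ratio gave -0.11 for the interaction. The chaperone list median in the central area after dissection was -0.0603 with median centring, still above the -0.15 of all genes there. On scan day 2 alone that list reversed to -0.0724, and on scan day 1 alone the muscle list reversed to -0.0352. Of 1420 values of named genes in other settings, 33 lost and 3 gained a call and 0 called values reversed. With each array left out, 30 of 1386 lost and 1 gained a call and 0 reversed. Most of these values belong to genes not called in the main fit, which cannot lose a call. Over all settings, Calca lost its call between normal areas in 16 of 37, Dner in 10 of 37, Foxa2 in 9 of 36 and Pcsk2 in 7 of 37. Scg3 lost it there in 5 of 37, Chgb in 3 of 36 and Cxcl13 in 2 of 37.

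The replicate number as a fixed replicate block gave 4 genes and 2 lists between normal areas and 84 genes between dissected areas, and as a random block 51 and 116 genes. The fixed block ended the calls of Calca (adjusted p = 0.115), Foxa2 (0.0660), Dner and Pcsk2 (0.0644 each) between normal areas. Whether the numbers pair the samples stays open. Between normal areas, with 3 pairs, correlations of same-numbered deviations reached down to -0.07. Between the dissected areas the lowest was 0.07, and 5 of 5 central arrays correlated best with their own number, as a hint from the data alone. These arrays also shared slides, so number and slide cannot be told apart there. Normal peripheral and dissected central arrays, which differ in state and area, correlated at 0.185 on average on the same slide. With the same number they correlated at 0.148. Between the dissected areas the mean was 0.152, so a shared slide alone may give correlations as high, and the hint of pairing is weak. Signal limits these results too, since 24.7% to 44.0% of probes were well above background.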

Other observations

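The tests of averaged effects, of the stem and progenitor list without Foxa2, of slides for the C cell list and of scan days for the chaperone list were chosen only after the results were seen.

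Averaged over both states, 209 genes differed between areas by limma, 205 of them higher in the central area. The 4 that were lower were Cp, the copper-carrying ceruloplasmin (-0.81, adjusted p = 0.00607), Dgkg, a diacylglycerol kinase (-0.73, adjusted p = 0.0118), Greb1, an oestrogen-regulated gene (-0.55, adjusted p = 0.0343), and Acy3, an aminoacylase (-0.66, adjusted p = 0.0478). Averaged over both areas, limma called 0 genes for dissection, with 1031 at an unadjusted p under 0.05 and a smallest adjusted p of 0.131. Mcpt4, a mast cell protease, was higher in the central than the peripheral area of dissected thyroid (log2 1.75, adjusted p = 0.00987), with a difference of 0.04 in normal thyroid. The interaction for Mcpt4 had an adjusted p of 0.79 and so was not called. Outside the C cell list, genes that rose in the centre in both states included Pnoc, a neuropeptide precursor (2.32 and 2.98), Abcc8, a subunit of the potassium channel of endocrine cells (2.58 and 2.51), and Aldh1a2, a retinoic acid synthase (2.33 and 2.31). The homeobox genes Hoxb7 (2.64) and Hoxb8 (1.89) were called in dissected thyroid, with differences of 1.62 and 1.36 in normal thyroid that were not called.

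The mean of the stem and progenitor list was higher in the central area by 0.35 in normal and 0.28 in dissected thyroid, with p = 7.09e-05 by exact permutation within states, the smallest the design can give. Without Foxa2 the 14 other genes gave 0.16 and 0.08 with p = 0.0688 by the same exact permutation, so the difference rests in good part on Foxa2. The Cy3 intensity of the brighter Calca probe was lowest on dissected central 4, at 18233, and highest on normal peripheral 1, at 494049, although Cy3 held the same reference on every array. Its Cy5 intensity on these arrays was 442440 and 117591. The second probe of Pcsk1 gave -0.16 and 0.54 where the brighter one gave 2.45 and 2.98.

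C cell genes were higher in the central area in both states, with p = 7.09e-05 by exact permutation within states (7.79e-04 adjusted over 22 lists). Weaker arrays in one area are argued against, since without the 4 weak arrays the smaller of both list medians was 2.43. Slide or scan day is argued against by a higher central mean in each of 8 comparisons within a slide, 3 in normal and 5 in dissected thyroid, on 5 slides. Nerve tissue in the central captures is argued against by a Schwann cell list of 12 genes, whose larger median was -0.0784, with 0 members called and S100b highest at 0.70. A higher share of C cells in the central captures may thus be put forward as a hypothesis, but neither it nor any other biological explanation was tested. How many C cells a capture held was not measured.

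The chaperone list mean was higher after dissection by 0.17 in the central area (p = 0.373 by exact permutation) and by 0.49 in the peripheral area (p = 0.0179, the smallest that 5 against 3 arrays can give), so the p of 0.0152 by exact permutation within both areas rests mainly on the periphery. Weaker arrays are argued against, as without them the smaller of both medians was 0.25. A shift common to a scan day is argued against in the central area, as day 1 held 2 of 5 arrays of each central group (difference in share 0), although the central median on day 2 alone was -0.0724. In the peripheral area the lower of both medians within a day was 0.33, which also speaks against it, but day 1 held only 1 normal peripheral array. Genes of this list moving together from array to array stay open, because the list is 1 of 22 tested, of which the C cell list, lower after dissection, had a smaller p (0.00659, adjusted 0.145), and the p adjusted over them was 0.168, so that the bound of 0.05 on the raw p that had been set for excluding this was too lenient. Dissection itself may be the source, which these values do not settle.

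Other splits of the same arrays into groups of the same sizes were compared with the real ones. Chance is unlikely for the 41 genes between normal areas. That count was reached by 1 of 56 splits, the real split, with 3 as the highest other. Chance is also unlikely for the 86 genes between dissected areas and the 155 genes among the 4 groups. Each count was reached by 1 of 100 splits, with 46 and 8 as the highest others. For the normal areas, 1 of 56 is the smallest share that these arrays can give. The shares were not corrected for the number of patterns tested. Splits also treat arrays as exchangeable, although areas may share animals, so chance is not excluded. The split with 46 exchanged dissected central 2, where C cell genes were low, with dissected peripheral 1, both of them weak arrays. A count of 0 is reached by every split by construction, so splits test nothing for dissected against normal central (100 of 100, at most 1 gene in another split), the peripheral comparison (56 of 56, at most 8), the interaction (100 of 100, at most 4) or its 0 lists (100 of 100, at most 12). Chance cannot be excluded for the number of lists shifted, with 4 in the central area after dissection (37 of 100 splits, at most 9), 2 in the peripheral area (44 of 56, at most 8), 1 between normal areas (53 of 56, at most 9) and 2 between dissected areas (86 of 100, at most 10). Splits with several times the real number of lists point to a structure of the arrays that moves the genes of a list together.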
